A study of Mus musculus with 6 samples.

How the data were processed

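RNA was measured in mouse embryonic fibroblasts (MEFs) from C57BL/6 embryos that were passaged in culture and harvested at population doubling (PD) 2, 8 and 14. A population doubling is the log2 of the ratio of cells counted to cells seeded, summed over passages. Each of the 3 groups had 2 libraries, 6 in all. Per the labels, replicate 1 of each group was a strand-specific library made after removal of ribosomal RNA, and replicate 2 was made by poly(A) enrichment. Replicate number and library method were therefore the same thing. They are called the rRNA-depleted and the poly(A) libraries here. The labels give no sign that the libraries came from separate cultures, so every p-value below is limited to these 6 samples. Those of single genes measure only the spread between the samples.

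The authors deposited TPM, transcript abundance scaled to a common sum per library, for each gene in a table of 21988 gene symbols. Their processing notes name bcl2fastq, cutadapt 1.14, HISAT2 2.0.5 and StringTie 1.3.1c with the mm10 genome build, without the role of each tool or the gene annotation. The deposited TPM of the poly(A) libraries summed to 1000000 each. Those of the rRNA-depleted libraries summed to 937922 at PD2, 950531 at PD8 and 937217 at PD14. These were 93.8%, 95.1% and 93.7% of 1000000, so part of each rRNA-depleted library is not in the table. TPM carry no read numbers, so the depth of each library and the counting error of each value are unknown.

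Gene positions were taken from GENCODE release M21. Of the symbols, 21506 matched 1 gene each, 451 matched none and 31 matched several. Of the matched genes, 98.9% were annotated as protein-coding. Genes of the same family and genes that overlap share reads, so single values of such genes are uncertain.

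Values were analysed as log2(TPM + 1) in R 4.3.3 with limma 3.58.1. Because of the added 1, fold changes of genes with low TPM are understated. Genes with a TPM of at least 1 in at least 2 of the 6 libraries were tested, which left 13332; 4062 genes were at 0 in every library. The linear model had a term for each group and library method as an additive block, with a mean-variance trend. It left 2 residual degrees of freedom, and limma's prior added 3.22. The tests were PD14 against PD2, PD8 against PD2, PD14 against PD8, the difference of the late step from the early step, and an F test of any change among the 3 groups. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, with a threshold of 0.05. Errors written ± are the standard error (SE) of the fitted log2 change, with n = 2 libraries per group.

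Before the data were examined, the tests, the alternatives, 24 gene lists and the rule for naming genes were fixed. The lists were CDK inhibitors and growth-arrest regulators; cytokines and chemokines, proteases and their inhibitors, and growth factors and binding proteins of the senescence-associated secretory phenotype (SASP); DNA replication and S phase; mitosis and G2/M; replication-dependent histones; p53 targets; NF-kappaB and C/EBP genes; AP-1 and related transcription factors; enhancer cofactors with cohesin and CTCF; interferon-stimulated genes; fibrillar matrix and fibroblast genes; contractile and YAP-responsive genes; lysosome; NRF2 and oxidative stress; imprinted fetal growth genes. The rest held markers of macrophages and leukocytes, endothelium, epithelium, neural and glial cells, skeletal and cardiac muscle, chondrocytes and osteoblasts, and erythroid cells. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the 23 lists tested. Camera compares the genes of a list with the other genes tested. At that preset correlation genes are taken as nearly independent. Its p-values therefore rest mainly on the spread over genes and not on that between samples. The erythroid list had 0 of its 15 members past the filter on TPM and was not tested. Camera with a correlation estimated from the residuals, and fry, which asks whether the genes of a list moved on balance in 1 direction, were run beside it. Members past the gene-level threshold were counted over all genes tested and, separately, adjusted over the list alone.

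The genes named for each comparison were the 12 with the largest rise and the 12 with the largest fall among those past the threshold. They had to have the same sign in both library methods and a mean TPM of at least 5. Predicted genes, mitochondrial genes, small RNAs and replication-dependent histones were passed over. Where fewer than 5 genes passed, the 10 with the smallest unadjusted p in each direction were named instead, as values that did not pass unless stated. A fixed panel of senescence genes and the 2 members of each list with the largest change were added whatever their result. Other members of the lists are named as examples because they passed the test. Some of the genes that these rules select are not reported here, and the counts over alternatives leave them out.

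The test was checked on simulated data built from the spread of these libraries, with 200 genes changed in each of 5 draws. For PD14 against PD2 it called 23.2% of genes changed by a log2 of 1, 79.2% at 2 and 97.6% at 3, and 5.81% of its calls were false. For PD14 against PD8 it called 2.8% at a log2 of 1, 30.4% at 1.5 and 64% at 2. For PD8 against PD2 it called 3.6%, 31.2% and 62.8% at the same sizes. In the simulation each gene's spread was drawn from limma's prior, genes varied independently, and the library methods differed by a fixed amount per gene. In the data genes can vary together, and some moved in opposite directions in the methods. These rates therefore need not hold for the data.

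The alternatives were no replicate block, a pseudocount of 0.1, no filter on low values, a filter on the mean TPM within each library method, median-of-ratios scaling within each method, quantile normalization, no mean-variance trend, each library left out in turn, and the estimated correlation in camera. A rescaling of every library to a sum of 1000000, with and without the mitochondrial genes, was added after the data were seen. The change within each library method rests on 1 library per group, so it has no replicate and no test of its own.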

Results

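The series measured gene expression in mouse embryonic fibroblasts at population doublings 2, 8 and 14. Its title places the question in senescence, the lasting arrest of division that cultured fibroblasts reach, and in the secretory phenotype (SASP) of senescent cells. Each group had 1 rRNA-depleted and 1 poly(A) library. Between 12554 and 12827 genes had a TPM of at least 1 in a library. Libraries of the same method correlated across genes at 0.925 to 0.982 on the log2 scale, and libraries of the same group made by the other method at 0.932 for PD2, 0.909 for PD8 and 0.873 for PD14. Transcripts of mitochondrial genes took 6.82%, 5.57% and 6.00% of TPM at PD2, PD8 and PD14 in the rRNA-depleted libraries and 6.74%, 4.35% and 3.04% in the poly(A) libraries.

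PD14 was compared with PD2 to ask what changed over the whole passage series. The largest rise was that of Lcn2, which encodes the iron-scavenging protein lipocalin 2 (chromosome 2, 32384633 to 32388252 on mm10), by a log2 of 6.13 ± 0.36 (adjusted p = 0.0125). Its TPM were 6.97, 209 and 407 at PD2, PD8 and PD14 in the rRNA-depleted libraries and 0.880, 30.7 and 179 in the poly(A) libraries. C3, the central complement component (chromosome 17, 57203970 to 57228136), rose by 4.85 ± 0.21 (adjusted p = 0.0117), from 8.96 to 360 TPM and from 3.70 to 107 TPM in the respective methods. The largest fall was that of Des, desmin of muscle, at -3.98 ± 0.28 (adjusted p = 0.0134), and Mki67, the proliferation marker Ki-67, fell by 2.18 ± 0.25 (adjusted p = 0.0203).

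Saa3, an acute-phase serum amyloid, rose by 4.95 ± 0.76 (adjusted p = 0.0277), the chemokine Cxcl15 by 4.94 ± 0.53 (adjusted p = 0.0184) and the complement protease C1rb by 4.45 ± 0.25 (adjusted p = 0.0125). Steap4, a metalloreductase, rose by 4.44 ± 0.32 and Lbp, which binds bacterial lipopolysaccharide, by 4.12 ± 0.28. The interferon-induced genes Iigp1, Ifit1 and Ifit3b rose by 4.40 ± 0.56, 4.11 ± 0.77 and 3.99 ± 0.86, and the protease inhibitor Serpina3n by 3.97 ± 0.32. Penk, the precursor of enkephalin peptides, rose by 4.15 ± 0.39, from 247 to 6283 TPM in the rRNA-depleted libraries and from 17.2 to 225 TPM in the poly(A) libraries. Saa3, C1rb, Serpina3n, Iigp1, Ifit1 and Ifit3b have close relatives in the mouse genome, so reads can be divided between copies and their single values are uncertain. The adjusted p of the genes in this paragraph lay between 0.0125 and 0.0483.

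Des encodes an intermediate filament (chromosome 1, 75360329 to 75368579). Its TPM went from 33.5 to 1.19 in the rRNA-depleted libraries and from 48.5 to 2.13 in the poly(A) libraries. Crabp1, a cellular retinoic acid binding protein, fell by 3.65 ± 0.45 (adjusted p = 0.0208). F2rl1, a protease-activated receptor, changed by -3.34 ± 0.58, and the gap junction gene Gjb2 by -3.24 ± 0.47. The amino acid transporter gene Slc38a4 changed by -2.91 ± 0.50, Lrrc15 by -2.85 ± 0.60, Tfpi2, an inhibitor of serine proteases, by -2.51 ± 0.33, and the lipid transporter gene Mfsd2a by -2.49 ± 0.21. The keratin gene Krt19 changed by -2.45 ± 0.47 and Depdc1a by -2.35 ± 0.51. Chchd10, a mitochondrial protein gene, changed by -2.57 ± 0.35, but 155 bases of it overlap Mmp11 on the opposite strand, so its value is uncertain. The adjusted p of these genes lay between 0.0134 and 0.0489.

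Of the fixed panel of senescence genes, 16 were tested and 5 passed. Cdkn2a, which encodes the cell-cycle inhibitors INK4a and ARF, rose by 2.63 ± 0.21 (adjusted p = 0.0166), from 40.2 to 190 TPM and from 62.1 to 519 TPM. Lmnb1, lamin B1 of the nuclear lamina, fell by 2.07 ± 0.22 (adjusted p = 0.0184), and Hmgb2, a chromatin protein, fell by 1.78 ± 0.21 (adjusted p = 0.0206). Igfbp3, which binds insulin-like growth factors, rose by 1.91 ± 0.23 (adjusted p = 0.0206), and Mki67 was the fifth. The inhibitor genes Cdkn2b and Cdkn1a were at 0.80 ± 0.20 (adjusted p = 0.0650) and 0.50 ± 0.26 (adjusted p = 0.251), and Trp53 at -0.54 ± 0.19 (adjusted p = 0.127). For the inflammatory genes Il6, Cxcl1, Ccl2, Mmp3 and Mmp13 the fitted values were -0.31, 3.08, 1.73, 3.32 and 0.72, with adjusted p between 0.0577 and 0.832. Their values differed between methods: Il6 was at -2.23 in the rRNA-depleted and 1.61 in the poly(A) libraries, Mmp13 at -2.36 and 3.79, and Cxcl1 at 0.99 and 5.17. Igfbp5 and Gdf15 were at -1.55 and 0.82 (adjusted p = 0.169 and 0.199). Il1a was below the filter, at 0 in every rRNA-depleted library and at most 0.515 TPM in a poly(A) library.

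**Figure D1:**
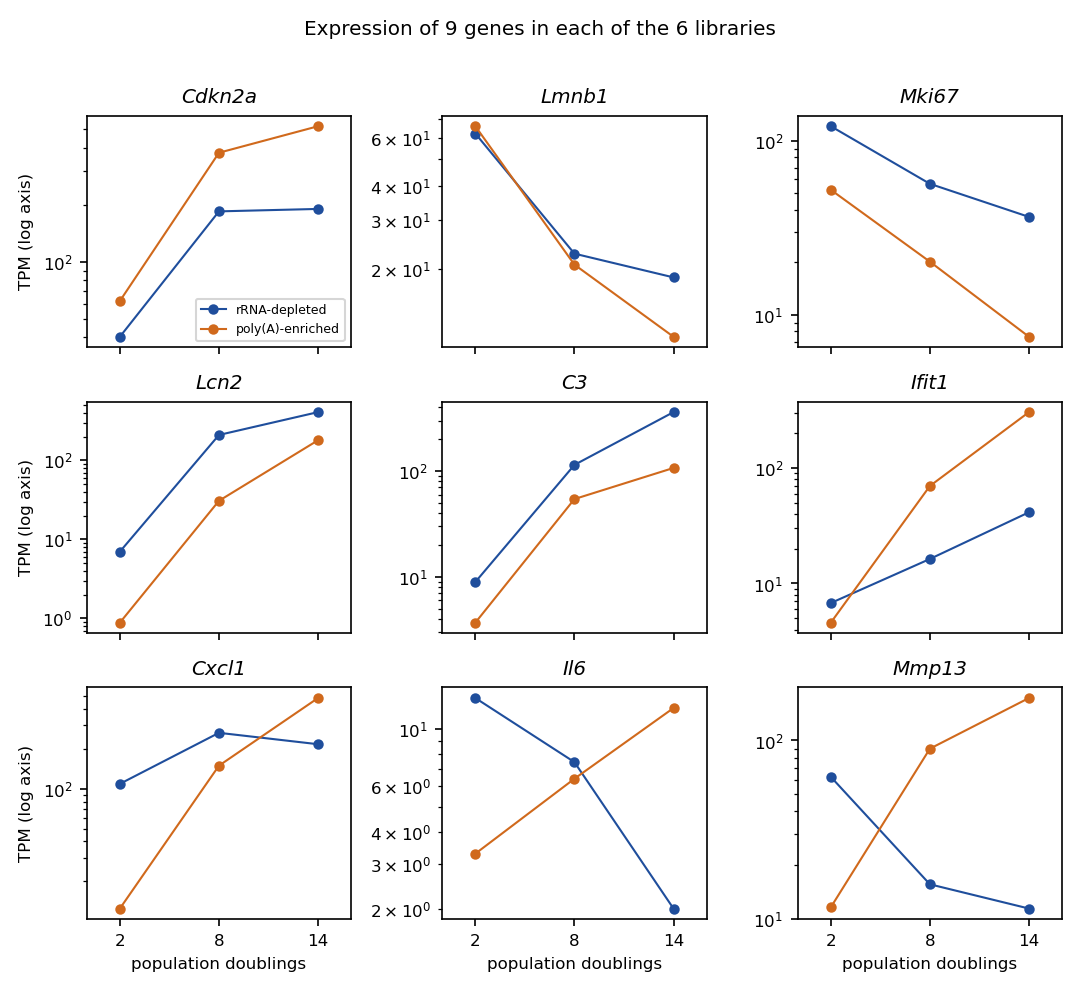
TPM on a log axis against population doublings for 9 genes, with 1 point per library and 1 line per library method. Cdkn2a, Lcn2, C3 and Ifit1 were higher and Lmnb1 and Mki67 lower at PD14 than at PD2 in both methods, while Il6 and Mmp13 had opposite signs of change in the methods.

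Genes of cell division fell as lists. All 42 tested genes of mitosis and G2/M had negative values in both methods and 36 of them fell, all 42 adjusted over the list alone, with a median of -1.63. Examples were the cyclin gene Ccna2 (-2.16 ± 0.30; 510 bases overlap Exosc9), the kinase gene Plk1 (-1.95 ± 0.20) and Birc5, a survival and mitosis protein (-1.90 ± 0.17). Of 40 genes of DNA replication and S phase, 26 fell (33 adjusted over the list alone), with a median of -1.05, among them Uhrf1, a factor that maintains DNA methylation (-2.17 ± 0.26), and the replication licensing gene Cdc6 (-1.91 ± 0.22). Camera gave adjusted p = 2.95e-25 for mitosis and 9.91e-18 for S phase. With an estimated correlation both had adjusted p = 0.483. Of 25 CDK inhibitors and growth-arrest regulators, 2 rose and 5 fell (4 and 8 adjusted over the list alone). Besides Cdkn2a, Rbl2, a relative of the retinoblastoma protein, rose. Lmnb1, Hmgb2, the chromatin regulator Ezh2 and the architectural genes Hmga1 and Hmga2 fell. The list had a median of -0.11, camera adjusted p = 0.0410, and adjusted p = 0.483 with an estimated correlation. Its call was lost without the rRNA-depleted library of PD2 (median -0.19) or of PD14 (median -0.11).

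Interferon-stimulated genes rose as a list, with a median of 2.36 and camera adjusted p = 3.02e-12 (adjusted p = 0.519 with an estimated correlation). Of 35 tested members, 18 rose and 0 fell (30 and 0 adjusted over the list alone; limma, all 35 fitted values were positive). They included the antiviral genes Isg15 (3.58 ± 0.74) and Ifit1, the transcription factor gene Irf9 (1.40 ± 0.23), and the immunoproteasome gene Psmb8 (2.88 ± 0.24). The median was 1.33 in the rRNA-depleted libraries and 3.57 in the poly(A) libraries. Beside it, macrophage and leukocyte markers had a median of -1.20 in the rRNA-depleted and 0.64 in the poly(A) libraries. Of those 20 markers 0 passed in limma, also adjusted over the list alone, and the list had adjusted p = 0.0931 (fitted median -0.27). It passed as lower without the poly(A) library of PD2 (median -1.27) or PD14 (median -0.73), and without the PD2 rRNA-depleted library its direction turned (median 0.58). Its 2 largest values were those of the complement genes C1qa and C1qc (-1.62 and -1.43).

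Secreted factors of the SASP were higher as lists, by smaller margins. Of 32 cytokines and chemokines, 6 rose and 0 fell (8 and 1 adjusted over the list alone), with a median of 1.34, camera adjusted p = 0.000771, and adjusted p = 0.565 with an estimated correlation. The 6 were the neutrophil chemokines Cxcl5 (3.54 ± 0.35) and Cxcl15, the interleukins Il15 (1.60 ± 0.30) and Il18 (1.48 ± 0.28), the chemokine Cx3cl1 (1.36 ± 0.29) and Csf1, a growth factor of macrophages (1.63 ± 0.33). The median was 0.13 in the rRNA-depleted and 2.01 in the poly(A) libraries. Of 34 growth factors and binding proteins, 9 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.48, camera adjusted p = 0.0181, and adjusted p = 0.483 with an estimated correlation. Hgf (1.90 ± 0.22), Fgf7 (1.68 ± 0.26) and Vegfd (2.08 ± 0.20), growth factors for epithelium and vessels, rose, placental growth factor Pgf fell by 1.32 ± 0.27, and Igfbp2 was at 3.03 ± 0.87 without passing. Of 23 proteases and inhibitors, 7 rose and 0 fell (8 and 2 adjusted over the list alone), with a median of 0.47, camera adjusted p = 0.0410, and adjusted p = 0.567 with an estimated correlation. They were the matrix proteases Mmp2 (1.52 ± 0.15), Mmp19, Adamts1 and Adamts5 and the inhibitors Serpine2 (2.15 ± 0.23), Timp2 and Timp3. All 3 calls were lost without the PD14 poly(A) library (medians 0.42 for cytokines, 0.25 for growth factors and 0.31 for proteases). Without the PD2 poly(A) library the cytokines (0.35) and proteases (0.12) were lost too, and the proteases also without either PD8 library (0.47 each).

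Lists of regulators of inflammation and of enhancers had medians from -0.41 to 0.55. Of 21 NF-kappaB and C/EBP genes, the adhesion molecules Icam1 (1.87 ± 0.12) and Vcam1 (1.76 ± 0.19) rose and 0 fell, also adjusted over the list alone. The list had a median of 0.55, camera adjusted p = 0.00495, and adjusted p = 0.519 with an estimated correlation; the call was lost without the PD14 poly(A) library (median 0.33). Of 25 AP-1 and related factors, Maf rose (1.10 ± 0.15) and Ets1 (-0.93 ± 0.16) and Ets2 (-0.83 ± 0.15) fell, also adjusted over the list alone. The list had a median of -0.41, camera adjusted p = 0.0254, and adjusted p = 0.542 with an estimated correlation; Fosb and Atf3, its largest values, were at -2.85 ± 1.60 and -1.98 ± 0.61 and did not pass. Without the PD2 rRNA-depleted library its call was lost (median -0.28), and without the PD14 rRNA-depleted library the direction turned (median 0.14). Of 33 enhancer cofactors and cohesin genes, the cohesin subunit gene Rad21 fell (-0.63 ± 0.11), 0 did adjusted over the list alone in limma, and Med14 was at -0.58 ± 0.17. The list had a median of -0.10, camera adjusted p = 0.0409, and adjusted p = 0.565 with an estimated correlation. Its call was lost without the poly(A) library of PD2 (median -0.06) or PD14 (median -0.05), without the block, and under quantile normalization.

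The p53 target list did not pass (median 0.24, adjusted p = 0.154), with 3 of its 30 genes higher and 1 lower, also adjusted over the list alone. The death receptor gene Fas rose by 2.13 ± 0.37, the repair gene Ercc5 by 0.82 ± 0.12 and the peptide transporter gene Tap1 by 1.80 ± 0.29 (212 bases overlap Psmb9), while Eda2r fell by 0.65 ± 0.14. The NRF2 and oxidative stress list did not pass either (median 0.11, adjusted p = 0.423). There 5 of 30 genes rose and 1 fell (6 and 1 adjusted over the list alone), among them the ferritin gene Fth1 (1.75 ± 0.28) and the glutathione transferase gene Gstm1 (1.19 ± 0.15). Of 36 lysosomal genes 5 rose and 1 fell, also adjusted over the list alone. Cathepsin F gene Ctsf rose by 2.43 ± 0.23 and cathepsin C gene Ctsc fell by 2.30 ± 0.35. The lysosome list had a median of 0.20, camera adjusted p = 0.0269, and adjusted p = 0.709 with an estimated correlation. Its call was lost without the poly(A) library of PD2 (median 0.07) or PD14 (median 0.20). Without the PD14 rRNA-depleted library the p53 list (median 0.27) and the NRF2 list (median 0.31) passed, as the NRF2 list did without the PD2 rRNA-depleted library (median 0.33). Without the poly(A) library of PD2 or PD14 the NRF2 median was -0.16 or -0.20, and without that of PD14 the p53 median was 0.04.

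Matrix and contractile genes moved apart. Of 32 fibrillar matrix and fibroblast genes 3 rose and 0 fell (6 and 1 adjusted over the list alone): the collagen gene Col3a1 (1.35 ± 0.19) and the proteoglycan genes Dcn (1.72 ± 0.18) and Lum (1.92 ± 0.27). The list had a median of 0.31, camera adjusted p = 0.0410, and adjusted p = 0.483 with an estimated correlation. Its call was lost without any of the 6 libraries, with medians from 0.28 to 0.33. Of 20 contractile and YAP-responsive genes 0 rose and 4 fell (0 and 8 adjusted over the list alone): Des, the actin gene Actg2 (-1.88 ± 0.18), the tropomyosin gene Tpm1 (-0.90 ± 0.17) and Ankrd1 (-2.19 ± 0.48). That list had a median of -0.39, camera adjusted p = 0.000196, and adjusted p = 0.537 with an estimated correlation. Imprinted fetal growth genes had a median of -0.49 and did not pass (adjusted p = 0.0666). Of 19, Dcn rose and Slc38a4 and Grb10, an adaptor of growth factor receptors, fell (2 and 3 adjusted over the list alone), and the growth factor gene Igf2 was at -2.58 ± 0.91. The imprinted list passed without the rRNA-depleted library of PD2 (median -0.56) or PD14 (median -0.70) or either PD8 library (median -0.49 each), and without the filter on low values (-0.50), and its median ranged from -0.70 to -0.19 over all settings and left-out libraries.

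Markers of cell types other than fibroblasts moved beside these lists. Only some passed the filter on TPM: 9 of 19 muscle, 9 of 18 neural, 6 of 16 epithelial and 9 of 16 endothelial markers. Of the chondrocyte and osteoblast markers 17 of 22 did. Epcam, Cdh1, Pecam1, Myod1 and Snap25 were among those below the filter. The lists therefore rest on their expressed members and do not by themselves show that these cell types were present. Of 9 skeletal and cardiac muscle markers 0 rose and 4 fell (0 and 7 adjusted over the list alone), namely Des, Acta1, Tnnt3 and Myh3, with a median of -1.32, camera adjusted p = 4.97e-05, and adjusted p = 0.483 with an estimated correlation. Actc1 was at -1.98 ± 0.46. Of 9 neural and glial markers the filament gene Nes (-2.26 ± 0.28) and the growth cone gene Gap43 (-2.18 ± 0.43) fell and Map2 rose by 1.59 ± 0.34 (1 higher and 4 lower adjusted over the list alone), with a median of -0.74, camera adjusted p = 0.0204, and adjusted p = 0.483 with an estimated correlation. Of 6 epithelial markers the keratin genes Krt18 (-2.42 ± 0.31) and Krt19 fell (1 higher and 3 lower adjusted over the list alone), with a median of -1.20, camera adjusted p = 0.0410, and adjusted p = 0.483 with an estimated correlation. Of 17 chondrocyte and osteoblast markers the cartilage matrix gene Matn4 rose by 2.40 ± 0.50 (149 bases overlap Rbpjl) and 0 did adjusted over the list alone in limma. That list had a median of 0.69, camera adjusted p = 0.0367, and adjusted p = 0.620 with an estimated correlation. Its cartilage genes Lect1 and Comp were at 3.32 ± 1.32 and 2.66 ± 0.62, and its median was 1.43 in the rRNA-depleted and 0.18 in the poly(A) libraries. Of 9 endothelial markers the VEGF receptor genes Kdr (-1.38 ± 0.24) and Flt1 (-0.75 ± 0.17) fell, also adjusted over the list alone, Erg was at -1.09, and the list did not pass (median -0.04, adjusted p = 0.151). The neural call was lost without the PD14 rRNA-depleted library (median -0.89), the chondrocyte call without the rRNA-depleted library of PD2 (0.46) or PD14 (0.38), and the epithelial call without the PD2 poly(A) library (-0.83) or either PD14 library (-1.32 and -1.08).

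The replication-dependent histone list gave opposite signs in the library methods. Its median was -1.97 in the rRNA-depleted and 0.86 in the poly(A) libraries, with a fitted median of -0.64, camera adjusted p = 0.0410, and adjusted p = 0.709 with an estimated correlation. Of 21 genes 0 passed in limma, also adjusted over the list alone; Hist1h3g and Hist1h3c, the largest values, were at -1.29 ± 0.47 and -1.27 ± 0.34. The call turned without the rRNA-depleted library of PD2 (median 0.50, adjusted p = 0.0267) and was lost without that of PD14 (median 0.17, adjusted p = 0.434), and 3 of the 10 settings that keep all libraries kept it.

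**Figure D2:**
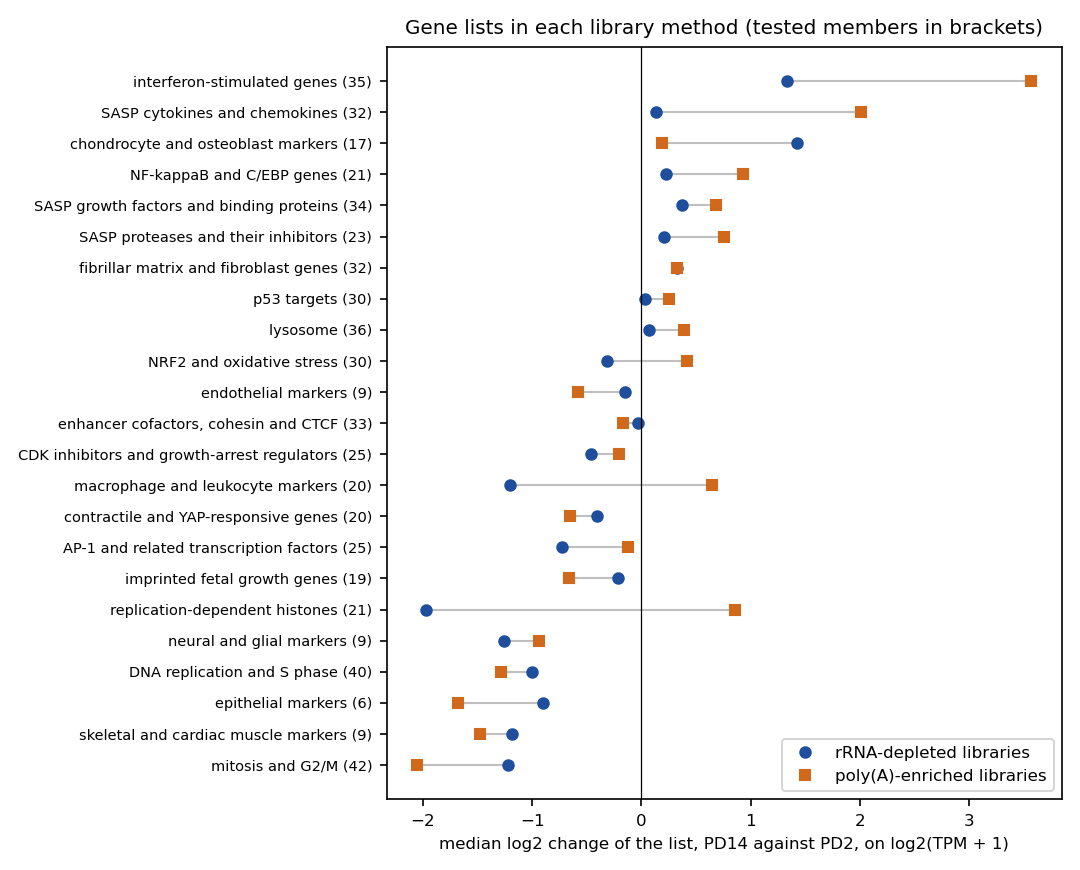
Median log2 change of each gene list from PD2 to PD14 within the rRNA-depleted libraries (circles) and the poly(A) libraries (squares), with the number of tested members in brackets. Interferon-stimulated genes were at 1.33 and 3.57, mitosis genes at -1.22 and -2.05, and the histone and macrophage lists lay on opposite sides of 0.

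In limma 1490 of 13332 genes passed between PD14 and PD2, 854 higher and 636 lower, and 4266 had an unadjusted p under 0.05 where 667 were expected by chance. The median size of change of the genes that passed was a log2 of 1.23, and all 1490 had the same sign in both library methods, which passing with 1 library per group and method nearly requires. With quantile normalization 736 passed as higher and 834 as lower, so the balance of rises and falls depended on the scaling. Without the replicate block 0 genes passed in limma (1516 at an unadjusted p under 0.05), without the filter on low values 404, and without the mean-variance trend 938. Without the PD14 rRNA-depleted library 0 passed, without the PD14 poly(A) library 5, and without the rRNA-depleted or the poly(A) library of PD8 25 or 21; these fits had 1 residual degree of freedom. Of 50 genes that were named by the rule and passed, all 50 lost their call without the block and without the PD14 rRNA-depleted library, 48 without the PD14 poly(A) library, 42 without either PD8 library and 22 without the filter, among them Saa3, Iigp1, Ifit1, Ifit3b, Slc38a4, Lrrc15, Krt19, Depdc1a and Ankrd1. Without the trend 10 lost it: Ifit1, Ifit3b, Slc38a4, Lrrc15, Krt19, Depdc1a, Fas, Rad21, Ankrd1 and Gap43. With a pseudocount of 0.1 Lrrc15, Depdc1a and Ankrd1 lost it, with quantile normalization Ifit3b and Lrrc15, after rescaling Ankrd1, and after rescaling without mitochondrial genes Depdc1a. Over all settings and left-out libraries, values ranged from 2.65 to 5.57 for Ifit1, 2.47 to 5.51 for Ifit3b, -4.00 to -1.70 for Lrrc15, -3.18 to -1.53 for Depdc1a, -3.06 to -1.31 for Ankrd1, -3.80 to -2.20 for Krt18 and -2.98 to -1.38 for Gap43. Of the 10 settings that keep all libraries, the list of CDK inhibitors and growth-arrest regulators kept its call in 4. The matrix list kept its call in 6, the enhancer list in 7, and the protease and chondrocyte lists in 8 each. The epithelial list kept its call in 4 of 9. Over all settings and left-out libraries, medians ranged from 1.39 to 3.28 for interferon-stimulated genes and 0.35 to 2.01 for cytokines. Those of growth factors ranged from 0.25 to 0.67, of proteases from 0.12 to 0.79 and of NF-kappaB genes from 0.29 to 0.84. Lysosome medians ranged from 0.07 to 0.42 and those of chondrocyte markers from 0.38 to 1.23. For the mixed list of CDK inhibitors and growth-arrest regulators the range was -0.48 to -0.11, and for enhancer cofactors -0.19 to -0.05. Medians of contractile genes ranged from -0.74 to -0.29, of neural markers from -1.13 to -0.38 and of epithelial markers from -2.52 to -0.35. Muscle marker medians ranged from -2.05 (pseudocount of 0.1) to -0.67 (no filter). With fry, the matrix (adjusted p = 0.0239) and neural (adjusted p = 0.00362) lists passed; mitosis (adjusted p = 0.0743), S phase (adjusted p = 0.0562), interferon-stimulated genes (adjusted p = 0.167), cytokines (adjusted p = 0.320) and the other lists did not.

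The library methods were compared gene by gene, because each change rests on 1 pair of libraries per method. From PD2 to PD14 the change correlated between methods across 13332 genes at a Pearson r of 0.517 and a Spearman rho of 0.520. Of these genes 69.6% had the same sign (95% exact binomial interval 68.8% to 70.4%). Genes are not independent replicates, so that interval is too narrow and no p-value is given. At least 2-fold higher in both methods were 502 genes, where 109 were expected if the methods were unrelated, and 339 were lower in both (48.9 expected). In opposite directions were 62 genes (146 expected). From PD2 to PD8 r was 0.496, rho 0.509, 69.4% of genes had the same sign, and 22 moved at least 2-fold in opposite directions (46.0 expected). From PD8 to PD14 r was 0.153, rho 0.141, and 52.7% had the same sign; 44 genes were at least 2-fold higher in both methods (5.20 expected), 9 lower in both (1.58 expected) and 21 opposite (5.74 expected), so there opposite changes too were more frequent than expected.

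**Figure D3:**
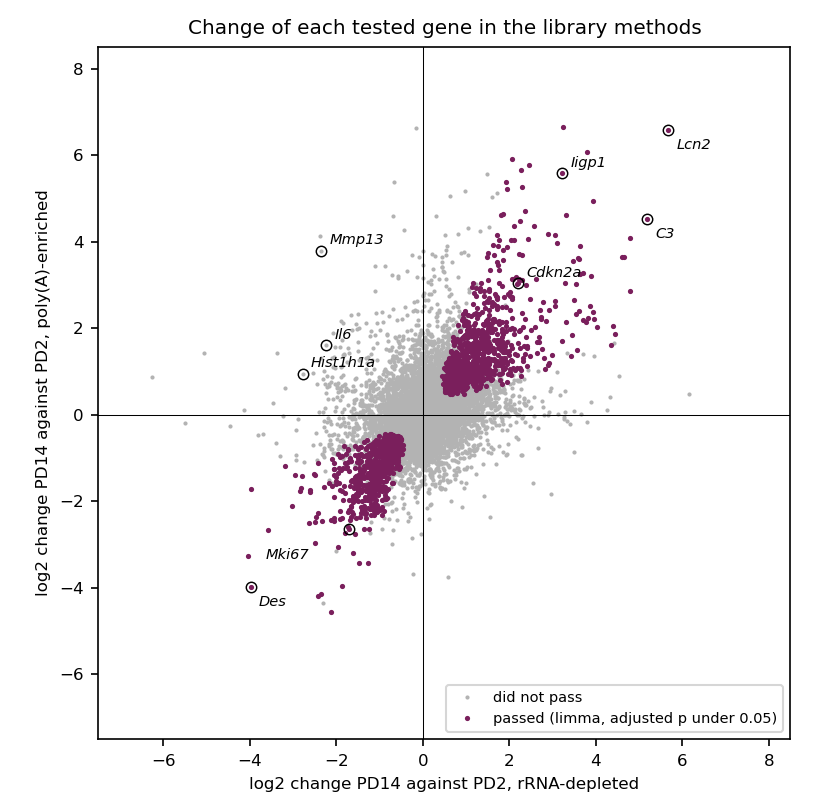
Log2 change of each tested gene from PD2 to PD14 in the rRNA-depleted libraries (x axis) and in the poly(A) libraries (y axis); coloured points passed in limma. All 1490 coloured points had the same sign in both methods, and Il6 and Mmp13 are among the genes with opposite signs.

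PD8 was compared with PD2 to ask what had already changed early in the passage series. C1s1, a protease that starts the complement cascade, rose by 2.51 ± 0.12 (adjusted p = 0.0372), from 41.9 to 224 TPM in the rRNA-depleted and from 18.4 to 119 TPM in the poly(A) libraries. Rspo2, which enhances WNT signalling, rose by 3.01 ± 0.16 (adjusted p = 0.0372), and C3 rose by 3.55 ± 0.21 (adjusted p = 0.0411). Cdkn2a was at 2.37 ± 0.21 and just missed the threshold (adjusted p = 0.0529).

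The next highest genes by p did not pass, each with adjusted p = 0.0529. They were C1ra and C1rb, close copies of a complement protease gene (2.30 and 3.41), the hyaluronan gene Cemip (1.62), the pentraxin gene Ptx3 (2.49), the lipid phosphatase gene Plpp3 (2.13), Icam1 (1.47) and Rcan2, a regulator of calcineurin (1.82). The 10 lowest did not pass either, with adjusted p between 0.0694 and 0.0800. They were Des (-2.90), the transferrin receptor gene Tfrc (-1.42), the growth factor gene Mdk (-2.38), the desaturase gene Scd1 (-1.14) and 6 genes of sterol synthesis: Sqle (-1.15), Lss (-1.15), Fdps (-1.05), Mvd (-1.0), Cyp51 (-1.22) and Acat2 (-1.06). Fdps shares 1124 bases with Gm43738 and Cyp51 166 bases with Akap9. Of the senescence panel 0 of 16 genes passed in limma, with values from -1.71 for Igfbp5 to 2.37 for Cxcl1. Lmnb1 was at -1.52 ± 0.22 (adjusted p = 0.0846) and Mki67 at -1.21 ± 0.25 (adjusted p = 0.121).

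By list, 16 of 23 passed camera, and 0 did with an estimated correlation, where the smallest adjusted p was 0.413. The mitosis list fell with a median of -0.84 (camera adjusted p = 1.06e-20; 0 of 42 genes passed over all genes, 35 lower adjusted over the list alone). The S phase list fell with a median of -0.78 (adjusted p = 1.43e-16; 28 of 40 lower adjusted over the list alone). Interferon-stimulated genes rose with a median of 1.31 (adjusted p = 1.68e-07; 1 of 35 higher adjusted over the list alone), at 0.54 in the rRNA-depleted and 1.94 in the poly(A) libraries. Muscle markers fell with a median of -0.78 (adjusted p = 5.91e-06), as did neural (-0.68) and epithelial markers (-0.93), and macrophage markers with a median of -0.41 (adjusted p = 0.0118), at -1.40 and 0.51 in the respective methods. SASP cytokines (median 0.80, adjusted p = 0.00746), growth factors (0.44) and proteases (0.39), p53 targets (0.29), NF-kappaB genes (0.34), matrix genes (0.35) and lysosomal genes (0.16) rose as lists. Imprinted genes (-0.43) and enhancer cofactors (-0.13) fell as lists. Without the PD2 poly(A) library 9 of these calls were lost, with medians of -0.25 for cytokines, 0.35 for growth factors, 0.02 for proteases, 0.27 for p53 targets, 0.01 for NF-kappaB genes, -0.08 for enhancer cofactors, -0.28 for imprinted genes, -0.45 for epithelial markers and -0.0081 for lysosomal genes. Without the PD2 rRNA-depleted library the macrophage median turned to 0.42 and the matrix call was lost (median 0.28), and without the PD8 rRNA-depleted library the macrophage (-0.03), matrix (0.37), p53 (0.25) and NF-kappaB (0.23) calls were lost. Without the PD8 poly(A) library the lysosome (0.14) and epithelial (-0.47) calls were lost. With all libraries kept, the epithelial call held in 4 of 9 settings, and the enhancer call was lost without the block and the matrix call without the filter. Over all settings and left-out libraries, medians ranged from 0.36 to 2.08 for interferon-stimulated genes, 0.02 to 0.75 for proteases, 0.01 to 0.63 for NF-kappaB genes, -1.48 to -0.66 for muscle, -0.96 to -0.40 for neural and -1.63 to -0.38 for epithelial markers. With fry the matrix list passed (adjusted p = 0.00750) and no other did.

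No member of a tested list passed over all genes. The members with the largest change in each list, besides those named above, were the following. Higher at PD8 were Cxcl15 (4.30), Cxcl5 (2.77), Ifit1 (2.41), Isg15 (2.30), Igfbp2 (2.24), Mmp3 (2.22), Comp (2.21), Lect1 (2.09), Ctsf (1.71), Fas (1.61), Serpine2 (1.51), Lum (1.19), Cebpd (1.1), Tap1 (1.12), Fth1 (1.10) and Hist1h4h (0.95). Lower were Krt18 (-2.32), Actc1 (-2.03), Slc38a4 (-2.03), Gap43 (-1.89), Igf2 (-1.85), C1qa (-1.76), Nes (-1.74), Igfbp5 (-1.71), Ankrd1 (-1.67), Cdkn1c (-1.64), Gpx1 (-1.47), Ctsc (-1.41), Kif15 (-1.39), Mrc1 (-1.37) and Krt19 (-1.26). Eln (-1.22), Uhrf1 (-1.20), Cdc6 (-1.19), Hist1h3g (-1.11), Kdr (-1.0), Bach2 (-0.95), Atf3 (-0.91), Flt1 (-0.85), Rad21 (-0.52) and Smc3 (-0.45) were the other lower ones. Cebpd shares 562 bases with Spidr, so its value is uncertain.

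In limma 3 of 13332 genes passed between PD8 and PD2, all higher and all with the same sign in both methods, and 2713 had an unadjusted p under 0.05, 1594 higher and 1119 lower. Without the replicate block, without the filter, without the trend or with quantile normalization 0 passed, and with a pseudocount of 0.1 21 did. Without the rRNA-depleted or the poly(A) library of PD2 641 or 296 genes passed, and without any 1 of the PD8 and PD14 libraries 0 did.

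PD14 was compared with PD8 to ask what changed late. No gene passed, so the values that follow are levels of the genes with the smallest unadjusted p, each with adjusted p = 0.866. Higher at PD14 were the complement genes C1s1 (1.09 ± 0.12) and Serping1, an inhibitor of C1 proteases (1.42 ± 0.21), the peroxidase gene Gpx1 (1.36 ± 0.19), the angiotensin receptor gene Agtr2 (1.29 ± 0.16) and the matrix gene Dpt (1.19 ± 0.17). Nrep (1.08), Cpz (1.49), Gdpd2 (1.3), Emb (0.75) and the interferon-inducible gene Mndal (1.58) were the others. Lower at PD14 were the mitosis genes Aurka (-0.88 ± 0.17) and Birc5 (-0.93 ± 0.17), Hmga2 (-0.69 ± 0.11), the lipid synthesis genes Fdps (-0.78) and Scd1 (-0.83), and Glmp (-1.11), Sgsh (-1.58), Ap1ar (-0.90) and Fhl3 (-0.68). Emb, Mndal, Fdps, Glmp and Sgsh overlap another gene (by 686, 37, 1124, 1278 and 955 bases), so their values are uncertain. Of the senescence panel 0 of 16 genes passed in limma, with values from -0.97 for Mki67 to 1.10 for Mmp3; Cdkn2a was at 0.25 ± 0.21 (adjusted p = 0.963).

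By list, 7 of 23 passed camera and 0 did with an estimated correlation, where the smallest adjusted p was 0.719. The mitosis list fell further (median -0.77, camera adjusted p = 1.15e-30). Of its 42 genes, 24 were lower adjusted over the list alone and 0 over all genes. S phase also fell further (-0.38, camera adjusted p = 3.64e-14). Contractile genes fell as a list (-0.44, camera adjusted p = 1.96e-10). From PD2 to PD8 the contractile list had not passed (median -0.095, camera adjusted p = 0.145). Interferon-stimulated genes rose further (median 1.21, adjusted p = 2.15e-16), with Iigp1 at 2.13 ± 0.56 and Ifit3 at 1.77 ± 0.91. Their median was 0.73 in the rRNA-depleted and 1.61 in the poly(A) libraries, and it was 0.32 without the PD14 poly(A) library and 2.00 without the PD14 rRNA-depleted library. SASP cytokines (0.45, adjusted p = 0.0131), growth factors (0.16, adjusted p = 0.0131) and NF-kappaB genes (0.31, adjusted p = 0.00562) rose as lists, and macrophage markers did not pass (median 0.12, adjusted p = 0.396). Without the PD14 poly(A) library the cytokine median turned to -0.31 and that of NF-kappaB genes to -0.0027, and the growth factor call was lost (0.28). Without the PD8 poly(A) library the growth factor (0.20) and NF-kappaB (0.28) calls were lost, and without the block that of growth factors was. Over all settings and left-out libraries, medians ranged from -1.05 to -0.47 for mitosis, -0.73 to -0.24 for contractile genes and 0.14 to 0.35 for growth factors. With fry 0 lists passed (smallest adjusted p = 0.773).

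The members with the largest change in each list did not pass. Higher at PD14 were Ccl5 (1.88), Cxcl10 (1.60), Lect1 (1.23), Dcn (1.1), Dlk1 (1.07), Matn4 (1.06), Gsta4 (0.87), Angpt1 (0.84), Cd14 (0.78), Vcam1 (0.76), Ctsf (0.72), Cebpb (0.70), Esam (0.69), Tap1 (0.68), Adgre1 (0.64), Trp63 (0.43), Pds5a (0.36), Arid1a (0.34) and Stmn2 (0.33). Lower were Fosb (-3.21), Fos (-1.62), Ptgs2 (-1.39), Krt19 (-1.19), Acta1 (-1.13), Myl9 (-1.10), Des (-1.08), Ccna2 (-1.04), Uhrf1 (-0.97), Btg2 (-0.92), Ctsc (-0.88) and Fbn2 (-0.83). Erg (-0.73), Cdc6 (-0.72), Hist1h2ag (-0.66), Hist1h1a (-0.65), Hmgb2 (-0.64) and Nes (-0.52) were the other lower ones. Fosb and Fos fell only in the rRNA-depleted libraries, from 301 to 1.95 TPM and from 587 to 10.9 TPM. In the poly(A) libraries they went from 1.10 to 1.52 TPM and from 4.50 to 27.6 TPM. Cxcl10, Cebpb and Matn4 overlap Art3, Tmem189 and Rbpjl by 133, 312 and 149 bases, so their values are uncertain.

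In limma 0 of 13332 genes passed between PD14 and PD8, with 746 at an unadjusted p under 0.05 where 667 were expected by chance. In the test of the late against the early step 0 genes passed, with 566 at an unadjusted p under 0.05, so no gene was shown to change more in 1 step than in the other. Without the PD14 poly(A) library 1 gene passed in each of these tests, and without the PD2 rRNA-depleted library 3 passed in the test of the steps. The F test of any change among the 3 groups passed 195 genes (3223 unadjusted), all of them also called between PD14 and PD2. It passed 0 without the replicate block, and 908 and 569 without the rRNA-depleted and the poly(A) library of PD2. Without either PD8 library or the PD14 rRNA-depleted library it passed 0, and without the PD14 poly(A) library 2.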

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

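Of the tests in this part, those of leukocytes, of a separate culture behind each library method, of continued division and of the cell type markers were chosen only after the result was seen. Among the 16 tested panel genes and the 23 tested lists, those in which the rRNA-depleted and the poly(A) libraries moved in opposite directions from PD2 to PD14 were looked at again, if the change was at least 1 on the log2 scale in each method for a gene or at least 0.5 for a list median. These were 2 genes and 2 lists; smaller opposite changes were passed over. None of these differences was tested, because each method has 1 library per group. Il6 differed by 3.84 on the log2 scale (-2.23 in the rRNA-depleted and 1.61 in the poly(A) libraries). Mmp13 differed by 6.15 (-2.36 and 3.79). The median of the macrophage and leukocyte markers differed by 1.85 (-1.20 and 0.64), and that of the replication-dependent histones by 2.83 (-1.97 and 0.86).

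Interferon-stimulated genes rose in both methods, but by 2.24 more on the log2 scale in the poly(A) libraries. Scaling of the TPM and transcript length are argued against as the cause, since the difference was 2.24 after median-of-ratios scaling and 0% of 10000 lists matched on length and expression had one as large (highest 0.57). A larger share of leukocytes is argued against as the whole of the rise within the poly(A) libraries, since their markers were at a median of 0.64 there (SD 0.875, 20 genes), below the 3.57 of the interferon list. A leukocyte share that changed differently in the series behind each method is argued against for the part of the difference from PD8 to PD14, where the interferon list differed by 0.875 and the markers by -0.148 (SD of the members 0.376; Lyz2, their most abundant gene, by -0.623). It may account for the part from PD2 to PD8, where the interferon list differed by 1.39 and the markers by 1.91 (SD 0.925; Lyz2 by 3.51). Whether the interferon-stimulated transcripts came from leukocytes was not tested, and a response of leukocytes that were present stays open for both steps. A separate culture or passage series behind each method cannot be told apart from the method itself, and the median of 1.33 in the rRNA-depleted libraries shows only that the rise was present there too. A stronger interferon response of the fibroblasts at PD14 in the poly(A) series also stays open.

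Replication-dependent histone genes were lower at PD14 in 21 of 21 cases in the rRNA-depleted libraries and higher in 18 of 21 in the poly(A) libraries, where their median TPM were 2.17, 3.76 and 5.38 against 283, 99.1 and 59.5. The S phase list had a median of -1.285 in the poly(A) libraries, with 38 of 40 genes lower. This argues against cells of the poly(A) series that went on dividing, on the evidence of 1 library per group. The SE of 0.104 was taken over the genes of the list, so it is not an error between libraries. That poly(A) selection leaves out histone transcripts, which mostly lack a poly(A) tail, may account for the low poly(A) values: at PD2 the ratio of rRNA-depleted to poly(A) values was higher for the histones than for 9 polyadenylated histone variant genes by 6.56 on the log2 scale. Whether the rise within the poly(A) libraries came from more polyadenylated histone transcripts was not tested.

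Markers of cell types other than fibroblasts moved apart from PD2 to PD14. The lists did not all fall: of 17 chondrocyte and osteoblast markers 10 were higher in both methods and 0 lower in both. The highest list median exceeded the lowest by 2.69 (SE 0.641) in the rRNA-depleted and 2.33 (SE 0.70) in the poly(A) libraries. These were chondrocyte and neural markers in the former and macrophage and epithelial markers in the latter. The SE were taken over genes, with 1 library per group. The lists were taken up because they moved apart, and the extremes were picked from the same medians. That difference therefore cannot decide on a falling share of all other cell types alike. Other cells in the culture behind each method cannot be told apart from the method, since no library separates culture from method. The chondrocyte and osteoblast median was 1.43 in the rRNA-depleted and 0.185 in the poly(A) libraries, each from 1 library per group. A change of expression within the fibroblasts was not tested and stays open.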

How the results depend on the processing

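Rescaling to a sum of 1000000 (1461 genes), also without mitochondrial genes (1445), was added after the data were seen. Between PD14 and PD2, without the replicate block 0 genes passed (0 higher, 0 lower), without the filter 404 (229 and 175), and without the trend 938 (540 and 398). Between PD8 and PD2 these 3 settings and quantile normalization gave 0, and a pseudocount of 0.1 gave 21. The F test gave 0 in the same 3 settings and 309 with the filter within each method. Dropping the block put the difference between library methods into the residual spread; the cause of the other shifts was not tested. With the estimated correlation 0 lists passed in each comparison.

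With 1 library left out, which leaves 1 residual degree of freedom and assumes that the lone sample of a group varies like the others, counts ranged from 0 to 1804 for PD14 against PD2 (0 to 1180 higher, 0 to 624 lower), 0 to 641 for PD8 against PD2, 0 to 1 for PD14 against PD8, 0 to 3 for the steps and 0 to 908 for the F test. Lists passing ranged from 11 to 17, 10 to 18 and 8 to 14. The correlation between methods was 0.483 with a pseudocount of 0.1 and 0.554 with the filter within each method for PD14 against PD2, and 0.443 and 0.532 for PD8 against PD2; with that filter 70.6% and 70.5% of genes had the same sign.

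Among the reported results these turned; the cause was not tested. Il6 between PD8 and PD2 was at -0.020 with median-of-ratios scaling, -0.11 with quantile normalization and -0.012 without mitochondrial genes. With 1 library left out, values for PD14 against PD2 ranged from -0.82 to 0.14 for AP-1 genes, -0.20 to 0.33 for NRF2 genes, -1.27 to 0.58 for macrophage markers, -0.69 to 0.013 for endothelial markers (where the median turned, not the test), 0.038 to 0.27 for p53 targets (where the test turned, not the median), -1.73 to 0.50 for histones, -5.91 to 0.21 for Fosb, -1.85 to 1.22 for Il6 and -2.02 to 3.45 for Mmp13. For PD8 against PD2 they ranged from -0.0081 to 0.48 for the lysosome, -0.25 to 1.46 for SASP cytokines (where the median turned and the call was lost), -1.38 to 0.42 for macrophage markers, -3.04 to 0.61 for Eln, -1.32 to 1.36 for Il6 and -2.28 to 3.19 for Mmp13. For PD14 against PD8 they ranged from -0.0027 to 0.46 for NF-kappaB genes, -0.31 to 1.19 for SASP cytokines, -0.50 to 1.91 for Cebpb, -0.27 to 3.46 for Cxcl10 and -3.49 to 0.71 for Ptgs2. Counted over results and settings, values of named genes stayed on their side of the threshold with the same direction in 2107 cases. They lost a call in 300, gained one in 94 and reversed in 16, and lists did so in 598, 115, 10 and 11. The cases that stayed include results that passed neither before nor after, and only a result that had passed could lose its call. These counts therefore do not measure how stable the calls were. Of the 50 named genes that passed between PD14 and PD2, 50 lost their call without the block and 42 without either PD8 library. Depth is unknown, so its limits cannot be given.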

Other observations

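The gene groups in this part were chosen after the data were seen, so their tests are not independent of the genes that led to them; all values are for PD14 against PD2, with camera's p adjusted over 9 such groups. Genes of sterol synthesis and uptake fell together: 24 of 24 passed, with a median of -1.40 (-1.30 in the rRNA-depleted and -1.56 in the poly(A) libraries) and adjusted p = 1.40e-20 (adjusted p = 0.169 with an estimated correlation). They included Hmgcs1 (-1.56 ± 0.18) and Idi1 (-1.94 ± 0.22). Of 12 genes of fatty acid synthesis 9 fell, among them Scd1 (-1.98 ± 0.13) and Fasn (-1.06 ± 0.14), with adjusted p = 6.11e-09 (adjusted p = 0.169 with an estimated correlation).

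Of 16 complement genes 14 were tested and 11 rose, among them C1s1 (3.60 ± 0.12), Serping1 (3.17 ± 0.21) and Cfb (3.43 ± 0.35). The median was 2.95 (3.42 and 2.31 in the respective methods), with camera adjusted p = 1.53e-10 (adjusted p = 0.169 with an estimated correlation). Of 15 genes in an acute-phase group, which includes the receptor genes Il1r1 and Il6st, 11 were tested and all 11 rose. The median was 3.08, with camera adjusted p = 1.87e-09 (adjusted p = 0.169 with an estimated correlation). Of 13 genes of MHC class I antigen presentation 10 rose, with a median of 1.80 (1.18 in the rRNA-depleted and 2.35 in the poly(A) libraries) and adjusted p = 6.11e-09 (adjusted p = 0.261 with an estimated correlation), among them B2m (1.60 ± 0.29), H2-K1 (2.11 ± 0.20) and H2-D1 (2.41 ± 0.27), the last a pair with similar sequences. Of 49 ribosomal protein genes Rpsa fell; the group had a median of -0.37 and adjusted p = 3.98e-10 (adjusted p = 0.261 with an estimated correlation). Of 9 polyadenylated histone variant genes 3 fell, with adjusted p = 0.0291 (adjusted p = 0.254 with an estimated correlation).

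Of 10 immediate early genes 0 passed in limma, with medians of -2.50 in the rRNA-depleted and 0.49 in the poly(A) libraries and adjusted p = 0.0340 (adjusted p = 0.575 with an estimated correlation and 0.0688 after median-of-ratios scaling). Fos was at 396, 587 and 10.9 TPM at PD2, PD8 and PD14 in the rRNA-depleted libraries and at 9.72, 4.50 and 27.6 TPM in the poly(A) libraries. The mitochondrial gene mt-Atp6 was at 6592, 4408 and 1223 TPM in the rRNA-depleted and 6694, 471 and 367 TPM in the poly(A) libraries, and mt-Atp8, which overlaps it by 43 bases, at 6335, 4920 and 5434 and at 7408, 851 and 576 TPM. The neighbouring mt-Co2 was at 5857, 5091 and 5846 and at 6229, 2784 and 2144 TPM, and mt-Co3, on the other side, at 4788, 4629 and 5288 and at 5481, 4158 and 2632 TPM.

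A hypothesis for the fall of the sterol synthesis genes is that the cells sensed an excess of sterol, in which case genes switched on through LXR, a sterol receptor, may rise. The median of 8 LXR target genes was 0.179 (SE 0.391) in the rRNA-depleted and 1.06 (SE 0.342) in the poly(A) libraries, and 5 of 8 were higher in both. These SE were taken over the genes, with 1 library per group. Smpdl3a, Nr1h3 and Pltp rose, and the group had adjusted p = 0.105. The bound set before the test was a median above 0.5 in both methods, and the rRNA-depleted median did not reach it, so the prediction was not met. That median lies within its spread over the genes of both no change and 0.5, a comparison that was not part of the bound. The bound thus went against the hypothesis, but given that spread the hypothesis cannot be told apart from its absence.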
